A study of Mus musculus with 12 samples.

How the data were processed

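RNA from 4 mouse adipose depots was sequenced: interscapular brown fat (iBAT), supraclavicular brown fat (scBAT), inguinal white fat (iWAT) and epididymal white fat (eWAT). Each depot has 3 libraries, 12 in all, and per the labels they come from untreated male C57BL/6 mice aged 8 weeks. Total RNA was purified with a kit made for fatty and fibrous tissue and turned into TruSeq RNA libraries. The deposited table holds raw counts, a whole number of reads per gene symbol and library, and the authors applied no normalization to it. The labels list bcl2fastq 1.8.3, STAR 2.4.2a, Picard 1.119, HTSeq 0.6.1p1, edgeR and genome build mm10, without the role of each tool. They state neither the gene annotation nor the strand setting, so reads of overlapping genes on opposite strands cannot be assigned with certainty.

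The table has 23420 genes, of which 4004 have no count in any library. Total counts per library run from 17159401 to 29262554. Genes were kept by the filterByExpr function of edgeR on depot, which left 14898 tested genes holding at least 99.7% of the counts of each library. Levels are CPM values, read counts scaled to a common library size with TMM factors. Differences were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with robust dispersion estimates. All 12 libraries entered a single fit with a mean per depot and no other term, which leaves 8 residual degrees of freedom. Every p-value given as adjusted for a gene comes from this edgeR fit unless another tool is named, with Benjamini-Hochberg adjustment over all tested genes of a contrast and a threshold of 0.05. The biological coefficient of variation was 26.1% over all genes. Estimated within a depot, it was 12.1% in iBAT, 15.7% in scBAT, 42.8% in iWAT and 17.6% in eWAT.

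The contrasts were the mean of both brown depots minus the mean of both white depots, and each of the 6 pairs of depots. A gene was called selective for a depot when it passed the threshold as higher there against each of the other depots. Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01 and again with a correlation estimated for each list, both two-sided, with adjustment over the lists of a contrast. A list needed more than 2 tested members for this test. The lists were brown adipocyte thermogenic, classical brown depot, beige adipocyte, white adipocyte, pan-adipocyte, oxidative phosphorylation, tricarboxylic acid cycle, mitochondrial fatty acid oxidation, fatty acid synthesis, triglyceride synthesis and lipolysis, glucose uptake and glycolysis, creatine cycle, adipokines and batokines, the Hoxa, Hoxb, Hoxc and Hoxd clusters, other developmental transcription factors, fibrillar collagen and matrix, adipose progenitor, mesothelium, skeletal muscle, B cell, T cell and thymocyte, macrophage, endothelium, Schwann cell and nerve, surface epithelium, salivary gland, epididymis, erythroid, circadian clock, and immediate early and stress genes. Hoxc8 and Hoxc9 stand on more than a single list.

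The lists, the contrasts, the test, the alternatives listed as set in advance and the rule for naming genes were fixed before the data were examined. The rule took, for each contrast, the 6 genes with the largest log2 difference in each direction among those past the threshold, with a mean of at least 10 CPM in the higher depot and no overlap between the replicates of the sides. Predicted gene models and immunoglobulin or T cell receptor segments were counted but not named. It also took up to 4 members of each list with the smallest adjusted p and members past the threshold against the direction of most of their list. A fixed set was given in each contrast: Ucp1, Cidea, Dio2, Ppargc1a, Prdm16, Zic1, Lhx8, Tmem26, Tbx1, Hoxc9, Hoxc10, Lep, Adipoq and Wt1. For selective genes it took the 6 with the largest minimum of the 3 log2 differences, among those with a mean of at least 10 CPM in that depot. Predicted gene models and receptor segments were again not named. Where a gene has no count in a depot, the fold is a lower bound against a floor of 3 counts over the depot, and where it has few counts a 95% exact (Clopper-Pearson) counting interval is given. Intervals and floors cover counting error only.

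Distances between libraries are root mean square differences of log2 CPM with a prior count of 2. Positions come from the GENCODE annotation of GRCm38 and were used for nothing else. The tests were tried on simulated data made from these counts. Of 50 genes changed 4-fold, up or down, 48 were recovered in scBAT minus iBAT, 44 in iWAT minus eWAT and 46 in brown minus white. Of 50 changed 1.5-fold, 8, 4 and 24 were recovered. The changed genes had a mean of at least 50 counts per library, and each gene had the same spread in all depots. Recovery of genes with fewer counts, or with the larger spread of iWAT, was not simulated. The alternatives set in advance were DESeq2 size factors or upper quartile scaling inside edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, a term for the replicate number, the estimated correlation of camera, each library left out in turn, and fits of only the depots compared. The replicate number was tested as a block because the labels do not say whether equal numbers mean the same animal. A further 3 alternatives were chosen after seeing the data, each leaving out a pair of libraries that stood apart: iWAT 1 and 3, scBAT 1 and 2, and eWAT 2 and 3. Exact permutation tests used scipy 1.17.1. No library was left out of the reported values.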

Results

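Gene expression was measured by RNA sequencing in 12 libraries of mouse adipose tissue, 3 from each of 4 depots. The brown depots were the interscapular pad (iBAT) and the supraclavicular pad (scBAT), and the white depots were the inguinal, subcutaneous pad (iWAT) and the epididymal, intra-abdominal pad (eWAT). Total counts were 17751125, 17222539 and 17159401 in iBAT libraries 1 to 3 and 17555857, 19890543 and 18073423 in scBAT. They were 24411866, 21670017 and 25467294 in iWAT and 25998176, 23793792 and 29262554 in eWAT. The title of the series names the profiling of brown and white adipose tissue, and the comparisons ask how brown differs from white fat, how the brown depots differ from each other and how the white depots do. The labels do not say that the replicates are separate animals, and the p-values therefore measure the spread between samples. Levels are CPM values, read counts scaled to a common library size, given as mean ± SD with n = 3 libraries per depot, and differences are log2 values with their standard error (SE). The median log2 difference of all tested genes between brown and white fat was -0.09 with TMM scaling and -0.16 with upper quartile scaling. No named gene and no gene list past the threshold with either scaling changed direction between them, with iBAT against iWAT or eWAT not counted here.

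Brown libraries lay apart from white ones. The median distance between an iBAT and an scBAT library was 0.616 on the log2 scale (range 0.464 to 0.776), against 0.45 between iBAT libraries and 0.509 between scBAT libraries. Distances between brown and white depots had medians from 1.441, for scBAT and eWAT, to 1.766, for iBAT and iWAT. The white depots lay a median of 1.257 apart (range 0.77 to 1.545). The iWAT libraries differed from each other by a median of 0.983 and up to 1.301, more than the nearest iWAT and eWAT libraries did, while the eWAT libraries had a median of 0.534. The first principal component held 63.4% of the variance and the second held 21.6%.

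Brown fat against white fat showed the thermogenic genes far higher in both brown depots. Ucp1, which encodes the uncoupling protein of brown fat mitochondria (GRCm38 chromosome 8, 83290352 to 83298452), stood at 2174 ± 331 CPM (SD, n = 3) in iBAT and 1969 ± 420 in scBAT against 22.1 ± 8.66 in iWAT and 45.6 ± 36.5 in eWAT. Its log2 difference was 6.03 (SE 0.41, adjusted p = 5.61e-07). Dio2, the deiodinase that makes active thyroid hormone inside the cell, rose by 6.71 on the log2 scale (SE 0.32, adjusted p = 7.47e-08). Cidea, a lipid droplet protein, rose by 4.45 (SE 0.44, adjusted p = 7.42e-06), and Ppargc1a, a coactivator that drives mitochondrial genes, rose by 3.30 (SE 0.20, adjusted p = 2.22e-07). Prdm16, a transcriptional regulator of brown fat identity, rose by 1.87 (SE 0.25, adjusted p = 7.62e-05). Of 25 thermogenic genes tested, 24 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.15e-16, and adjusted p = 0.261 with an estimated correlation). The gene that fell was Adrb3, the beta-3 adrenergic receptor, at 235 ± 34.8 and 254 ± 62.6 CPM in iBAT and scBAT against 343 ± 170 and 934 ± 123 in iWAT and eWAT (log2 difference -1.21, adjusted p = 0.00121). The largest increases past the limits of the naming rule were in Lgr6 (7.25), Dio2, Kng2 (6.22), Ucp1, Slc27a2 (5.86), an acyl-CoA synthetase and fatty acid transporter, and Fabp3 (5.75), a fatty acid binding protein.

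**Figure D1:**
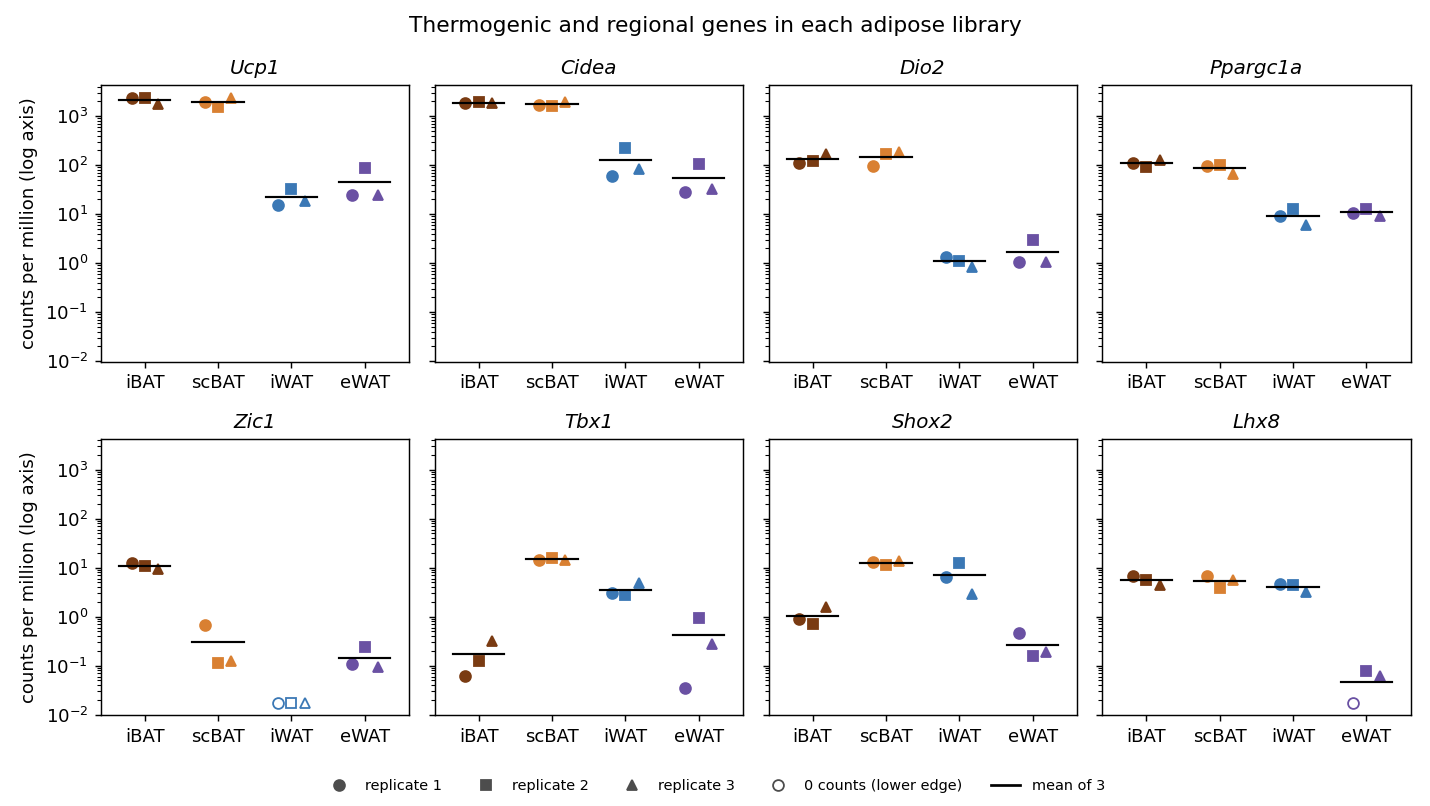
Levels of 8 genes in each of the 12 libraries, in CPM on a log axis, with symbols for replicates 1 to 3 and a line at the mean of 3. Ucp1, Cidea, Dio2 and Ppargc1a are high in both brown depots, while Zic1 is high in iBAT (11.03 CPM) and Tbx1 and Shox2 are higher in scBAT (14.8 and 12.7 CPM) than in iBAT.

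Genes of mitochondrial fuel use were higher in brown fat nearly without exception. Of 73 oxidative phosphorylation genes tested, 71 rose and 1 fell (72 and 1 adjusted over the list alone; camera adjusted p = 1.39e-38, and adjusted p = 0.294 with an estimated correlation). Ndufs8, a complex I subunit, stood at 383 ± 24.7 CPM in iBAT and 354 ± 30.1 in scBAT against 67.8 ± 14.1 in iWAT and 65.3 ± 7.88 in eWAT. The gene that fell was Atp5g1, which codes for the c subunit of the ATP synthase as its paralogs do (log2 difference -1.11, adjusted p = 3.83e-05). In the tricarboxylic acid cycle 16 of 17 genes rose, also adjusted over the list alone, among them Suclg1 (3.04) and Dlst (2.59) (camera adjusted p = 8.44e-14, and adjusted p = 0.294 with an estimated correlation). In mitochondrial fatty acid oxidation 19 of 20 genes rose and 1 fell, likewise over the list alone (camera adjusted p = 1.85e-10, and adjusted p = 0.4 with an estimated correlation). Acaa2 (3.47) and Acadvl (3.09) rose, while Cpt1a, the form of the carnitine transferase that prevails in liver, fell by 1.61 (adjusted p = 2.65e-08). Glucose uptake and glycolysis had 14 genes higher and 2 lower of 17, the same over the list alone (camera adjusted p = 7.35e-08, and adjusted p = 0.178 with an estimated correlation). Pgk1 (2.32) and Ldhb (3.28) were higher and the hexokinase gene Hk1 (-0.70) and the glucose transporter gene Slc2a1 (-0.77) were lower. Fatty acid synthesis had 13 higher and 2 lower of 16 (14 and 2 adjusted over the list alone; camera adjusted p = 0.000311, and adjusted p = 0.49 with an estimated correlation). Elovl6 (3.68) and Acly (2.18) were higher and the desaturase genes Fads1 (-1.71) and Fads2 (-0.75) lower. Triglyceride synthesis and lipolysis had 9 higher and 1 lower of 13, the same over the list alone (camera adjusted p = 0.0187, and adjusted p = 0.652 with an estimated correlation). Skeletal muscle markers, which mark a tissue rich in the same mitochondrial and glycolytic genes, moved with these groups. All 16 of them rose, also over the list alone (camera adjusted p = 4.57e-06, and adjusted p = 0.49 with an estimated correlation), and their median level ran from 21.4 to 305 CPM in brown libraries and from 2.07 to 12.7 CPM in white ones.

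White adipocyte markers were lower in brown fat for all 11 tested, also over the list alone (camera adjusted p = 2.94e-06, and adjusted p = 0.4 with an estimated correlation). Sncg fell by 4.72 on the log2 scale, Slc7a10 by 4.44 and Nnat by 4.71. Lep, the gene of the satiety hormone leptin, stood at 214 ± 98 and 329 ± 120 CPM in iBAT and scBAT against 746 ± 495 and 1138 ± 204 in iWAT and eWAT (adjusted p = 0.00157). Adipoq, the gene of the adipocyte hormone adiponectin, had a log2 difference of -0.42 (SE 0.20, adjusted p = 0.0775). Pan-adipocyte genes had 8 higher and 2 lower of 16 (camera adjusted p = 0.444), and adipokines and batokines had 3 higher and 5 lower of 10 (camera adjusted p = 0.525). Both counts were the same adjusted over the list alone, as were those of the creatine cycle, with 3 higher and 3 lower of 7 (camera adjusted p = 0.498), and of the beige adipocyte list, with 4 higher and 6 lower of 11 (camera adjusted p = 0.753). Tmem26, a surface marker of beige cells, fell by 4.64 (adjusted p = 3.59e-05), while P2rx5 rose by 3.89 (adjusted p = 1.86e-07). Classical brown depot genes had 8 higher and 1 lower of 11, the same over the list alone (camera adjusted p = 0.00311, and adjusted p = 0.294 with an estimated correlation). Mpzl2 (4.08) and Pdk4 (3.95) were higher and Epsti1 (-3.31) lower. Epsti1 was uneven in iWAT, at 159.6 ± 134 CPM, against 12.05 ± 0.762 in eWAT, 3.91 in iBAT and 4.99 in scBAT. The clock genes had 5 higher and 2 lower of 13 (camera adjusted p = 0.347), and immediate early and stress genes had 1 higher and 6 lower of 12 (camera adjusted p = 0.262), unchanged in number over the list alone.

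The Hox clusters went different ways between brown and white fat, where 69.4% of all genes were called. All 6 tested Hoxc genes were lower in the mean of the brown depots, also over the list alone (camera adjusted p = 0.00201, and adjusted p = 0.425 with an estimated correlation). However, Hoxc4 and Hoxc5 had a higher mean in iBAT (14.02 and 22.75 CPM) than in iWAT (5.12 and 10.88), and were low in scBAT (2.56 and 3.46). Hoxc8 (chromosome 15, 102990607 to 102994111) stood at 7.21 ± 0.832 CPM in iBAT and had 2 counts in all of scBAT, against 70.0 ± 38.6 in iWAT and 166 ± 8.01 in eWAT. Hoxc9 had 1 count in iBAT and 0 in scBAT, and was at least 147-fold higher in iWAT than in scBAT. The Hoxa cluster went both ways, with 4 higher and 4 lower of 9, over the list alone too (camera adjusted p = 0.469). Hoxa4 (2.94) and Hoxa5 (2.14) rose and Hoxa7 (-2.29) fell, and the mean difference of that list was negative where its median and test were positive. The Hoxb cluster had 2 higher and 5 lower of 8 (3 and 5 over the list alone; camera adjusted p = 0.0874), and the Hoxd cluster had 3 lower of 5, the same over the list alone (camera adjusted p = 0.207). Of the fixed genes, Zic1 (adjusted p = 4.28e-05) and Lhx8 (3.56, adjusted p = 3.71e-06) rose, Hoxc9 (adjusted p = 3.33e-06), Hoxc10 (adjusted p = 0.0008) and Wt1 (adjusted p = 5.51e-05) fell, and Tbx1 had a log2 difference of 0.40 (adjusted p = 0.557). However, Zic1 was high in iBAT alone (11.03 CPM), Hoxc10 in iWAT alone (20.9) and Wt1 in eWAT alone (19.8). Lhx8 was low in eWAT alone (0.0473 CPM, against 4.13 in iWAT). Other developmental transcription factors had 8 higher and 8 lower of 18, the same over the list alone (camera adjusted p = 0.58), with Gata6 (-3.04) among the latter.

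**Figure D2:**
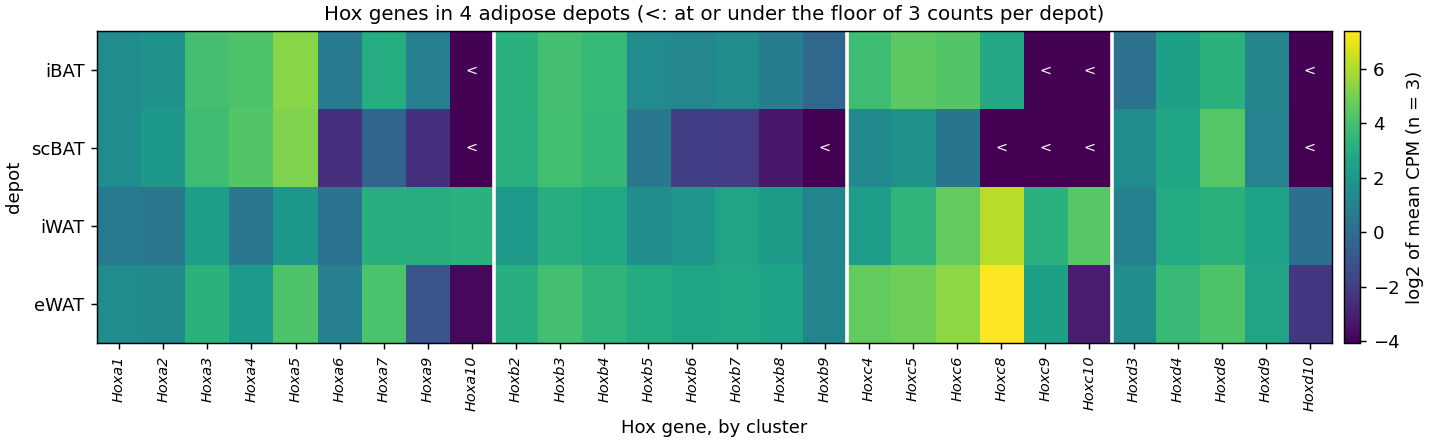
Mean level of each tested Hox gene in the 4 depots as log2 CPM (n = 3 libraries), ordered by cluster, with a mark where the depot is at or under the floor of 3 counts. Levels are lower in scBAT than in iBAT from Hoxa6 to Hoxa9, Hoxb6 to Hoxb9 and Hoxc4 to Hoxc8, and Hoxc10 is high in iWAT alone (20.9 CPM).

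Markers of other cell types also differed between brown and white fat. All 12 macrophage markers fell in brown fat, also over the list alone, and this list passed with an estimated correlation too (camera adjusted p = 3.76e-10, and adjusted p = 0.0433 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, stood at 27.6 ± 4.47 and 50.4 ± 3.81 CPM in iBAT and scBAT against 171 ± 12 and 195 ± 3.63 in iWAT and eWAT. Fibrillar collagen and matrix genes fell in 15 of 16 cases (camera adjusted p = 0.000211, and adjusted p = 0.599 with an estimated correlation), and adipose progenitor genes had 1 higher and 8 lower of 11 (camera adjusted p = 0.0187, and adjusted p = 0.4 with an estimated correlation). Mesothelium markers fell in 8 of 10 (camera adjusted p = 0.000195, and adjusted p = 0.294 with an estimated correlation). All 10 B cell markers and all 11 T cell markers fell, but their level differed within iWAT. The B cell median was 219, 11.8 and 303 CPM in iWAT libraries 1 to 3 and at most 4.31 CPM in any library of another depot, and limma-voom called 0 of either list (edgeR had all 10 and 11 at an unadjusted p under 0.05, and DESeq2 called 10 and 11). Their camera adjusted p was 0.0118 and 0.00708, and 0.645 for each with an estimated correlation. Endothelium had 4 higher and 4 lower of 11 (camera adjusted p = 0.816). Schwann cell and nerve markers had 3 higher and 1 lower of 8 (camera adjusted p = 0.301). Surface epithelium had 3 lower of 8 (camera adjusted p = 0.469) and salivary gland 6 higher of 8 (camera adjusted p = 0.0874). Epididymis had 1 higher and 1 lower of 2, and erythroid genes 2 higher of 2. All of these counts were the same adjusted over the list alone.

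Brown and white fat differed in 10333 of 14898 tested genes (69.4%), with 4657 higher and 5676 lower in brown fat, of which 1978 and 3308 differed at least 2-fold. The largest falls were in Upk3b, Chst4, Marco, Upk1b, Col6a4 and Wt1, which had at most 5 counts in either brown depot. Marco and Col6a4 were high in the lymphocyte-marked iWAT 1 and 3, Marco at 99.3, 5.81 and 135 CPM in iWAT 1 to 3. Of 155 named genes past the threshold, 152 passed without each of the 12 libraries in turn, 155 with DESeq2 and 143 with limma-voom, and the direction changed in 0 of them. With iWAT libraries 1 and 3 left out, an alternative chosen after seeing the data, the count of higher salivary genes went from 6 to 0, and the camera adjusted p of the B cell, T cell and triglyceride lists became 0.184, 0.0755 and 0.0609.

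Between the brown depots, scBAT against iBAT, Hox genes and some other developmental genes were called and none of the thermogenic list. Tbx1, a T-box transcription factor of the neck and pharynx (chromosome 16, 18580979 to 18590671), stood at 14.8 ± 0.835 CPM (SD, n = 3) in scBAT and 0.17 ± 0.136 in iBAT (log2 difference 6.41, SE 0.83, adjusted p = 0.0113). Zic1, a zinc finger factor of the dorsal somite (chromosome 9, 91358058 to 91365810), went the other way, at 11.03 ± 1.61 CPM in iBAT and 0.307 ± 0.326 in scBAT, a ratio of 36.7 (95% counting interval 22.0 to 66.0, adjusted p = 0.0148). Its neighbour Zic4, whose annotated span overlaps it, was also higher in iBAT (adjusted p = 0.0202). Shox2, a homeobox gene, was higher in scBAT (3.58, SE 0.56, adjusted p = 0.0251), as were Tbx18 (1.43, adjusted p = 0.0211), Nrn1 (1.69, adjusted p = 0.00599) and Akr1c13 (1.59, adjusted p = 0.00599). Lhx8 had like levels, 5.60 ± 1.1 CPM in iBAT and 5.39 ± 1.46 in scBAT (log2 difference -0.06, SE 0.35, adjusted p = 1). The beige adipocyte list, which holds Tbx1 and Shox2, had 2 higher of 11, also over the list alone (camera adjusted p = 0.000562, and adjusted p = 0.0271 with an estimated correlation), and the classical brown list, which holds Zic1, had 1 lower of 11 in both counts (camera adjusted p = 0.00835, and adjusted p = 0.295 with an estimated correlation). Other developmental transcription factors had 1 higher, Tbx18, and 1 lower, Zic4, of 18 (3 and 2 over the list alone; camera adjusted p = 0.862), with a positive median and a negative mean and test. Tbx1 lost its call without iBAT 1, iBAT 2 or scBAT 2 (adjusted p up to 0.121), Zic1 without iBAT 1, 2 or 3 or scBAT 2 (up to 0.109) and Nrn1 without iBAT 1 (0.0645). Zic4 and Tbx18 lost theirs without any library of iBAT or scBAT or without eWAT 1 or 3 (up to 0.152 and 0.166). Shox2 lost it without any library of iBAT or scBAT or without iWAT 1 or eWAT 3 (up to 0.2).

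Of the Hox genes called between the brown depots, all but Hoxd8 were lower in scBAT. Of the Hoxc cluster 4 of 6 tested genes fell, also over the list alone (camera adjusted p = 1.88e-39, and adjusted p = 0.00348 with an estimated correlation). Hoxc6 stood at 19.7 ± 0.25 CPM in iBAT and 1.31 ± 0.634 in scBAT (adjusted p = 0.00599), and Hoxc8 was 179 times higher in iBAT (counting interval 49.1 to 1480, adjusted p = 0.00599). The spans of Hoxc4, Hoxc5 and Hoxc6 overlap, so reads may be shared among them. Hoxc4 fell by 2.45 (adjusted p = 0.00787) and Hoxc5 by 2.71 (adjusted p = 0.0446). The Hoxb cluster had 4 lower of 8 (5 over the list alone; camera adjusted p = 4.72e-24, and adjusted p = 0.0233 with an estimated correlation), with Hoxb9 at least 14.3-fold lower in scBAT (adjusted p = 0.00599). The Hoxa cluster had 2 lower of 9 (3 over the list alone; camera adjusted p = 4.1e-10, and adjusted p = 0.0948 with an estimated correlation), Hoxa7 (-3.38) and Hoxa6 (-3.02), while Hoxa9 was not called (adjusted p = 0.0553). In the Hoxd cluster Hoxd8 was higher in scBAT (1.07, adjusted p = 0.0429), 1 of 5 genes (2 over the list alone; camera adjusted p = 0.00323, and adjusted p = 0.152 with an estimated correlation), and the mean of that list was negative where its median and test were positive. Hoxa7, Hoxb6, Hoxb7, Hoxb9, Hoxc6 and Hoxc8 passed without each of the 12 libraries in turn. Hoxc4 did not without iBAT 1, iBAT 2 or scBAT 2 (adjusted p up to 0.0684), nor did Hoxa6 without iBAT 1, iBAT 2, scBAT 1 or scBAT 2 (up to 0.0878). Hoxc5, Hoxb8 and Hoxd8 did not without any library but iWAT 2 and iWAT 3 (up to 0.241, 0.189 and 0.289).

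The thermogenic and metabolic lists held no called gene between the brown depots. Ucp1 had a log2 difference of -0.14 (SE 0.47, adjusted p = 1), Cidea of -0.11 (SE 0.54, adjusted p = 1), Dio2 of 0.17 (SE 0.34, adjusted p = 1) and Ppargc1a of -0.31 (SE 0.25, adjusted p = 1). Prdm16 had 0.46 and the hormone genes Lep and Adipoq had 0.62 and 0.05 (adjusted p = 1 each). Tmem26 had 2 counts in iBAT and 5 in scBAT (adjusted p = 1). Hoxc9, Hoxc10 and Wt1 were at or under the floor of 3 counts in both depots. Of 25 thermogenic genes edgeR called 0, with 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The camera test placed that list lower (adjusted p = 0.0149, and adjusted p = 0.753 with an estimated correlation). Of 73 oxidative phosphorylation genes edgeR called 0, with 1 at an unadjusted p under 0.05 and 1 over the list alone, DESeq2 called 1 and limma-voom 0. The camera test placed that list lower as well (adjusted p = 0.00458, and adjusted p = 0.836 with an estimated correlation). In simulated data of this size 28 of 50 genes with a 2-fold change and 8 of 50 with a 1.5-fold change were found, so smaller differences would mostly be missed. The tests of single genes also used a spread per gene shared by all depots, white ones included. Cidea, for example, stood at 1881 ± 27.6 and 1744 ± 146 CPM in iBAT and scBAT. In iWAT and eWAT it stood at 124.8 ± 91.3 and 55.08 ± 43.0 CPM, a larger spread relative to the mean. Genes that were not called are thus not shown to be equal between the brown depots.

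Several marker lists of other tissues and cells were higher in scBAT. Of 12 macrophage markers 5 rose (8 over the list alone; camera adjusted p = 3.35e-27, and adjusted p = 0.00301 with an estimated correlation), with DESeq2 calling 6 and limma-voom 3. C1qc, a complement gene of macrophages, stood at 39.5 ± 1.27 CPM in scBAT and 20.1 ± 2.92 in iBAT (log2 difference 0.98, adjusted p = 0.00609). Csf1r rose by 0.87 (adjusted p = 0.014) and C1qa by 0.88 (adjusted p = 0.0148). Clec10a, which is not on that list, rose by 1.57 (adjusted p = 0.0234). Of 8 salivary gland markers 1 rose (7 over the list alone; camera adjusted p = 7.92e-14, and adjusted p = 0.0348 with an estimated correlation), Aqp5, a water channel of gland cells (adjusted p = 0.0443), while DESeq2 called 4 and limma-voom 0. The salivary median was 174, 325 and 36.1 CPM in scBAT libraries 1 to 3 and at most 12 CPM in iBAT. Of 16 skeletal muscle markers edgeR called 0, with 13 higher and 1 lower at an unadjusted p under 0.05 and over the list alone (camera adjusted p = 4.52e-14, and adjusted p = 0.165 with an estimated correlation), while DESeq2 called 1 higher and 1 lower and limma-voom 0. Of 11 adipose progenitor genes edgeR called 0, with 6 at an unadjusted p under 0.05 and 4 over the list alone (camera adjusted p = 3.58e-10, and adjusted p = 0.0233 with an estimated correlation), while DESeq2 called 1 and limma-voom 0. C1qc lost its call without iBAT 2 (adjusted p = 0.0688) and Csf1r and C1qa without iBAT 1, iBAT 2, scBAT 1 or scBAT 2 (up to 0.121 and 0.134). Aqp5 and Clec10a lost theirs without any library but iWAT 2, iWAT 3 and, for Aqp5, scBAT 3 or, for Clec10a, iWAT 1 (up to 0.298 and 0.182).

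In all, 35 genes were higher and 14 lower in scBAT than in iBAT, 0.3% of those tested. These counts depended on single libraries, those of white depots included. With a block for the replicate number they became 10 and 8, and 12 named genes lost their call: Zic1, Zic4, Shox2, Tbx18, Hoxa6, Hoxb8, Hoxc5, Hoxd8, Csf1r, Clec10a, Itgam and Aqp5 (adjusted p from 0.0531 to 0.119). Without a library they became 3 and 7 (iBAT 1), 3 and 7 (iBAT 2), 17 and 9 (iBAT 3), 8 and 9 (scBAT 1), 6 and 7 (scBAT 2), 21 and 11 (iWAT 1), 121 and 24 (iWAT 2), 69 and 18 (iWAT 3), 19 and 10 (eWAT 1) and 14 and 10 (eWAT 3). Of the 24 named genes past the threshold, 7 passed in each of the 12 omissions, 24 passed with DESeq2 and 14 with limma-voom, and the direction changed in 0. DESeq2 called 181 genes higher and 29 lower and limma-voom 21 and 8. In the edgeR fit all depots share a spread per gene, on which the calls and each SE rest. Estimated within a depot, the biological coefficient of variation was 42.8% in iWAT against 12.1% in iBAT and 15.7% in scBAT. A fit of the brown depots alone gave 127 higher and 27 lower, and without scBAT 1 and 2, chosen after seeing the data, edgeR called 0 genes.

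Both brown depots differed from each white depot in many genes. Against iWAT, scBAT had 4192 genes higher and 4987 lower, and iBAT had 4155 higher and 5237 lower. Against eWAT, scBAT had 3880 higher and 3851 lower, and iBAT had 3901 higher and 4097 lower. The same genes recurred where the libraries of the contrasts did not overlap. All calls come from the same fit with a spread per gene shared by all depots. The calls of these contrasts are thus linked, and the counts for independent calls are only a reference. Of the genes higher in iBAT than in iWAT and those higher in scBAT than in eWAT, 3111 were shared, where independent calls would share 1082.1, and 2856 were shared among those lower, against 1353.7. Across genes, which are not independent replicates, the log2 differences of these contrasts had Pearson's r = 0.709. For iBAT against eWAT and scBAT against iWAT, 3089 higher and 2756 lower genes were shared, against 1097.7 and 1371.4, with r = 0.61. The thermogenic list rose in 24 of 25 genes in scBAT against iWAT (24 over the list alone; camera adjusted p = 2.46e-16, and adjusted p = 0.337 with an estimated correlation) and in 23 of 25 with 1 lower against eWAT (24 and 1 over the list alone; camera adjusted p = 1.53e-21, and adjusted p = 0.175 with an estimated correlation).

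Among the genes with the largest differences in these pairs were depot markers and transcripts that were high in single libraries. In scBAT against eWAT the largest increases were in Dio2 (6.49), Otop1 (6.19), a proton channel, Rpl39l (6.09), Slc27a2 (5.89), Acot11 (5.75) and Elovl3 (5.72). The largest falls were in Upk3b, Upk1b, Hoxc8, Wt1, Chst4 and Lrp2. In scBAT against iWAT the largest increases were secretory genes of salivary gland, Prp2, Dcpp1, Dcpp3, Chia, Scgb1b27 and Prb1, with log2 differences from 10.04 to 10.46 and an SD near or above the mean, as in Dcpp1 at 269.9 ± 210 CPM. Dcpp1 moved with the salivary median given for scBAT, at 263, 484 and 63.3 CPM in scBAT 1 to 3. The largest falls there were in Glycam1, which was at least 1720-fold higher in iWAT, Marco, Hoxc10, Dapl1, Serpina10 and Ngp, and all but Hoxc10 were high in iWAT 1 and 3 with the lymphocyte markers, as Marco, a scavenger receptor of macrophages, was. In iBAT against iWAT the largest increases were in Zic1, at least 301-fold, Lgr6 (9.10), Kng2 (7.60), Dio2 (6.94), Ucp1 (6.62) and Fabp3 (6.30). The largest falls were in Dsc3, Hoxc10, Col6a4, Ngp, Glycam1 and Alb, of which Dsc3, Col6a4, Ngp and Glycam1 were high in the lymphocyte-marked iWAT 1 and 3. In iBAT against eWAT the largest increases were in Lgr6 (6.36), Slc27a2 (6.35), Dio2 (6.32), Otop1 (6.23), Zic1 (6.22) and Kng2 (5.93), and the largest falls were in Upk3b, Msln, Upk1b, Slc5a1, Wt1 and Tnfrsf11b. Slc5a1, a glucose transporter of gut and kidney, rested on eWAT 3 (21.6 ± 37.3 CPM in eWAT), and it lost its call without that library, without iBAT 1, 2 or 3, scBAT 1, iWAT 1 or iWAT 2 (adjusted p up to 0.366).

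The 14 genes fixed for every contrast had these differences in scBAT and iBAT against iWAT and then in scBAT and iBAT against eWAT. Ucp1 had 6.48, 6.62, 5.44 and 5.58, Cidea 3.80, 3.91, 4.99 and 5.10, and Dio2 7.10, 6.94, 6.49 and 6.32. Ppargc1a had 3.27, 3.58, 3.03 and 3.34 and Prdm16 1.54, 1.08, 2.66 and 2.20, and all of these passed. Lhx8 passed against eWAT (6.68 and 6.73) and not against iWAT (0.38 and 0.44), and Tmem26 passed as lower in scBAT against iWAT (-6.30), in iBAT, where it had 2 counts, against iWAT and eWAT (adjusted p = 3.23e-05 and 0.0203), and not in scBAT against eWAT (-1.83, adjusted p = 0.0749). Tbx1 passed in scBAT against iWAT (2.07) and eWAT (5.15) and in iBAT against iWAT (-4.34), and not in iBAT against eWAT (-1.26, adjusted p = 0.261). Lep passed in all (-1.80, -1.79 and -2.41) but scBAT against iWAT (-1.18, adjusted p = 0.0739), and Adipoq only in iBAT against eWAT (-0.71, adjusted p = 0.0498). Zic1 passed in all but scBAT against eWAT (adjusted p = 0.244), Hoxc9 and Wt1 passed as lower in all, and Hoxc10 passed as lower against iWAT and not against eWAT (adjusted p = 0.122 and 0.125). Single omissions ended the calls of Tbx1 in scBAT against iWAT (iWAT 1, adjusted p = 0.0524), Prdm16 in iBAT against iWAT (iBAT 3, iWAT 1 or iWAT 3, up to 0.0714), and Tmem26 in iBAT against eWAT (iBAT 3 or eWAT 3, up to 0.0653). They also ended those of Lep in scBAT against eWAT (scBAT 2 or 3, up to 0.07) and in iBAT against iWAT (iBAT 2 or iWAT 2, up to 0.0598), and of Adipoq in iBAT against eWAT (any library but iWAT 2 and iWAT 3, up to 0.144).

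Among the genes lower in iWAT than in eWAT were those of the mesothelium, the cell layer that lines the abdominal cavity. Upk3b stood at 172 ± 13.2 CPM (SD, n = 3) in eWAT and 0.871 ± 0.89 in iWAT (log2 difference -7.59, SE 0.65, adjusted p = 0.0017). Msln, the gene of mesothelin (chromosome 17, 25748613 to 25754378), stood at 96.0 ± 20.2 against 0.379 ± 0.226 (-7.96, SE 0.54, adjusted p = 0.000165). Wt1, a transcription factor of mesothelium and visceral fat (chromosome 2, 105126529 to 105173616), was 162 times higher in eWAT (counting interval 87.8 to 338, adjusted p = 0.000631) and had 0 counts in both brown depots, at least 314-fold less than in eWAT. All 10 mesothelium markers were higher in eWAT, also over the list alone, and the list passed with an estimated correlation (camera adjusted p = 1.61e-32, and adjusted p = 0.00421 with an estimated correlation). Tcf21 (-6.42, adjusted p = 0.00199), Gata6 (-1.42, adjusted p = 0.00227) and Fgf1 (-3.16, adjusted p = 0.000631) were higher in eWAT too. Each of these genes passed without each of the 12 libraries in turn.

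The largest falls by the naming rule were in Krt8 (-7.99, adjusted p = 0.00337), Msln, Dcpp1 (-7.71, adjusted p = 0.023), Upk3b, Upk1b and Wt1, and some epithelial and salivary genes among the falls were uneven in eWAT. Krt8, a keratin gene on the mesothelium list, stood at 18.8, 16.7 and 98.1 CPM in eWAT 1 to 3 and the desmosome gene Dsp (-6.33, adjusted p = 0.0202) at 0.887, 1.55 and 13.6, while Dcpp1 stood at 1.24, 123 and 2.48. Of 8 salivary gland genes 4 were lower in iWAT, also over the list alone (camera adjusted p = 0.0228, and adjusted p = 0.642 with an estimated correlation): Dcpp1, Aqp5 (-7.66, adjusted p = 0.00406), Smr3a (-5.53, adjusted p = 0.0149) and Pip (-6.48, adjusted p = 0.0194). Of 8 surface epithelium genes 3 were lower and 1 higher in both counts (camera adjusted p = 0.0561). Krt14 (-7.20, adjusted p = 0.0017), Perp (-3.66, adjusted p = 0.00487) and Dsp were lower and Sfn (1.79, adjusted p = 0.0459) was higher. Dcpp1 lost its call without any iWAT library or eWAT 2 (adjusted p up to 0.0901), Pip without iWAT 1, iWAT 3 or eWAT 2 (up to 0.07), Dsp without iWAT 1, iWAT 3 or eWAT 3 (up to 0.0766) and Sfn without any library but iWAT 2 (up to 0.181).

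Some genes of body position differed between iWAT and eWAT, in both directions. Lhx8 stood at 4.13 ± 0.818 CPM in iWAT and 0.0473 ± 0.0418 in eWAT (log2 difference 6.30, SE 0.52, adjusted p = 0.000153). Tbx15 (4.93, adjusted p = 0.000801), Hoxa10 (6.98, adjusted p = 0.000631), Hoxa9 (4.12, adjusted p = 0.00131), Hoxc10 (7.53, adjusted p = 0.00338), Shox2 (4.72, adjusted p = 0.00147) and En1 (3.26, adjusted p = 0.00424) were higher in iWAT. Hoxa4 (-1.68, adjusted p = 0.00336), Hoxa5 (-2.22, adjusted p = 0.00029), Hoxc4 (-2.28, adjusted p = 0.00147), Hoxd8 (-0.97, adjusted p = 0.00679), Nr2f1 (-1.58, adjusted p = 0.00457) and Nr2f2 (-0.58, adjusted p = 0.00715) were lower. These genes passed without each of the 12 libraries in turn. The Hoxa cluster had 2 higher and 4 lower of 9 (2 and 6 over the list alone; camera adjusted p = 0.0915) and the Hoxc cluster 1 higher and 3 lower of 6 (1 and 4 over the list alone; camera adjusted p = 0.264), and the mean of both lists was positive where the median and test were negative. The Hoxb cluster had 5 lower of 8, also over the list alone (camera adjusted p = 0.0228, and adjusted p = 0.642 with an estimated correlation), and the Hoxd cluster 1 higher and 2 lower of 5 in both counts (camera adjusted p = 0.364). Other developmental transcription factors had 4 higher and 3 lower of 18 (5 and 5 over the list alone; camera adjusted p = 0.938), with a positive mean and a negative median and test.

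Some beige adipocyte genes and most of the nerve sheath genes tested were higher in iWAT, and neither list passed with an estimated correlation. The beige adipocyte list had 6 higher of 11, also over the list alone (camera adjusted p = 0.00599, and adjusted p = 0.14 with an estimated correlation), with Tmem26 at 8.30 ± 5.03 CPM in iWAT and 0.366 ± 0.118 in eWAT (4.47, SE 0.60, adjusted p = 0.00191). Klhl13 (16.1 against 25.7 CPM), Car4 (38.4 against 58.5) and Slc36a2 (200 against 219) had a lower mean in iWAT and were not called. Tnfrsf9, which activated lymphocytes also express, stood at 10.03 ± 7.37 CPM in iWAT. Of 8 Schwann cell and nerve genes 7 were higher (8 over the list alone; camera adjusted p = 1.57e-08, and adjusted p = 0.14 with an estimated correlation). Without iWAT 1 and 3 the Schwann list had 8 higher and the beige list 5.

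Lymphocyte genes were higher in iWAT but unevenly so. All 10 B cell and all 11 T cell markers were higher, also over the list alone (camera adjusted p = 1.75e-07 and 7.26e-09, and adjusted p = 0.511 for each with an estimated correlation), of which limma-voom called 4 and 2. The T cell median was 91.1, 6.47 and 154 CPM in iWAT 1 to 3 and at most 2.18 CPM in eWAT. Fcer2a, a receptor of mature B cells, stood at 184 ± 154 CPM in iWAT and 1.21 ± 0.932 in eWAT (7.21, SE 1.07, adjusted p = 0.00322), and Cd4 at 140 ± 117 against 2.37 ± 0.357 (5.89, SE 0.88, adjusted p = 0.0033). The largest increases, in Glycam1, Dsc3, Serpina10, Ngp, Nsg2 and Apol7c, had the same uneven pattern, and Glycam1, a mucin of the vessels by which lymphocytes enter lymph nodes, stood at 121, 7.66 and 159 CPM in iWAT 1 to 3. Of the 2631 genes higher in iWAT, 1306 (49.6%) were more than 2 times higher in both iWAT 1 and iWAT 3 than in iWAT 2, against 1.6% of the genes lower in iWAT and 13.5% of all tested genes. In 1744 of the 2631, iWAT 2 also lay above all eWAT libraries. Without iWAT 1 and 3, chosen after seeing the data, 1 B cell and 10 T cell markers were still higher, with iWAT then resting on 1 library that is assumed to vary like those of the other depots.

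**Figure D3:**
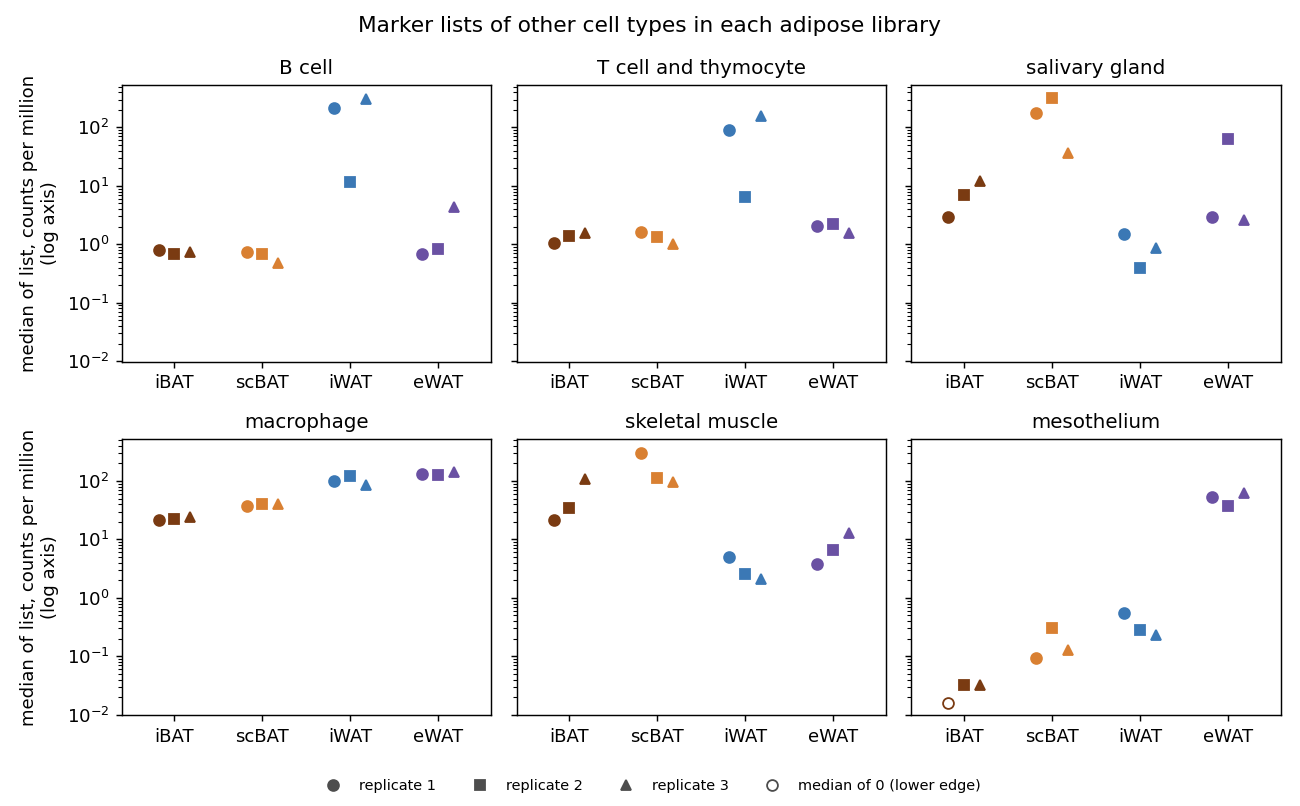
Median level of 6 marker lists in each of the 12 libraries, in CPM on a log axis, with symbols for replicates 1 to 3. B cell and T cell markers are high in iWAT 1 and 3 (B cell 219 and 303 CPM) and low in iWAT 2 (11.8 CPM), salivary gland markers are high in scBAT and in eWAT 2 (64.5 CPM), and mesothelium markers are high in eWAT alone.

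Adipocyte genes of the white depots depended on these libraries. Of 73 oxidative phosphorylation genes edgeR called 0 between iWAT and eWAT, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0981), and DESeq2 and limma-voom called 0. Without iWAT 1 and 3 the list had 9 higher in iWAT and the camera test placed it higher (adjusted p = 6.17e-15), the tricarboxylic acid cycle had 7 higher and fatty acid oxidation had 11 higher and 1 lower. White adipocyte genes had 4 lower of 11 in iWAT, also over the list alone (camera adjusted p = 0.000316, and adjusted p = 0.537 with an estimated correlation). Pan-adipocyte genes had 0 called of 16 by edgeR, with 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00905, and adjusted p = 0.642 with an estimated correlation), while DESeq2 called 3 lower and limma-voom 0. Thermogenic genes had 3 higher and 1 lower of 25 (1 and 1 over the list alone; camera adjusted p = 0.421). Prdm16 (21.1 ± 10.1 against 9.70 ± 2.05 CPM, adjusted p = 0.0402), Otop1 (2.31, adjusted p = 0.0219) and Acot11 (0.87, adjusted p = 0.041) were higher and Adrb3 (-1.45, adjusted p = 0.0171) was lower. Prdm16 lost its call without iBAT 1, 2 or 3, scBAT 2, iWAT 1 or 2 or any eWAT library (adjusted p up to 0.13), and Acot11 without any library but iWAT 1 and eWAT 2 (up to 0.132). Otop1 lost it without eWAT 1 or 3 (up to 0.0842) and Adrb3 without iWAT 1 or eWAT 1 (up to 0.0614). Tbx1 was higher in iWAT (3.08, adjusted p = 0.0128), not so without eWAT 3 (0.0527), and Zic1, with 0 counts in iWAT and 12 in eWAT, was lower (adjusted p = 0.031), not so without iWAT 1 or 3 or any eWAT library (up to 0.0821). Ucp1 had a log2 difference of -1.04 (SE 0.48, adjusted p = 0.114) and Cidea of 1.18 (SE 0.55, adjusted p = 0.117). Dio2 had -0.62 (adjusted p = 0.293), Ppargc1a -0.24 (adjusted p = 0.468) and Hoxc9 0.79 (adjusted p = 0.203). The log2 difference of Lep was -0.61 (SE 0.52, adjusted p = 0.369) and that of Adipoq -0.54 (SE 0.28, adjusted p = 0.149).

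Between the white depots 2631 genes were higher and 1646 lower in iWAT (28.7% of those tested). Without a white library these counts became 852 and 493 (iWAT 1), 5326 and 4997 (iWAT 2), 1065 and 838 (iWAT 3), 641 and 580 (eWAT 1), 957 and 761 (eWAT 2) and 872 and 619 (eWAT 3). Of the 106 named genes past the threshold, 58 passed in each of the 12 omissions, 106 passed with DESeq2 and 78 with limma-voom, and the direction changed in 0. DESeq2 called 3166 genes higher and 2492 lower and limma-voom 1426 and 1936. A fit of the white depots alone gave 48 higher and 162 lower. The biological coefficient of variation was 42.8% within iWAT against 26.1% in the fit of all depots. Adjusted p-values of contrasts with iWAT can thus be too small in that fit.

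Genes selective for a depot, higher there than in each of the other depots, numbered 1714 in iWAT, 1059 in eWAT, 9 in scBAT and 3 in iBAT. The iBAT genes were Zic1, Zic4 and Tmem200c, and only Zic1 met the naming rule, the others being named after their values were seen. The leading genes named for the other depots had a mean of at least 10 CPM there. For scBAT these were Tbx1, with a smallest log2 difference of 2.07, Aqp5 (1.99), Nrn1 (1.03), Tbc1d16 (0.86), Tbx18 (0.60) and Rsrc1 (0.42). Lhx1 lay below that level and was named after its values were seen. It had 219 counts in scBAT, 41.9 times the iBAT level (counting interval 17.7 to 130) and 376 times the eWAT level (66.8 to 14900). Against iWAT, with 0 counts, it was at least 120-fold higher. Aqp5 moved with the salivary transcripts, at 10.4, 30.1 and 2.47 CPM in scBAT 1 to 3 against 2.91, 5.27 and 2.70 in eWAT 1 to 3, and its difference between scBAT and eWAT was reversed without scBAT 1 and 2 (-0.54), an alternative chosen after seeing the data. The iWAT set was led by Glycam1, Serpina10, Ngp, Dsc3, Nsg2 and Apol7c, and 66.9% of it was more than 2 times higher in iWAT 1 and 3 than in iWAT 2, while in 1043 of its genes iWAT 2 also lay above all eWAT libraries. The eWAT set was led by Msln, Upk3b, Upk1b, Wt1, Bnc1 and Mgam. Bnc1, the gene of a transcription factor of epithelia, stood at 13.8 ± 2.76 CPM in eWAT, while Mgam, an intestinal and renal disaccharidase, stood at 76.9 CPM in eWAT 3 against 0.852 and 1.31 in eWAT 1 and 2. With a block for the replicate number the iBAT and scBAT counts of edgeR were 0 and 4. The iBAT count was 0 without iBAT 1, iBAT 2, iBAT 3 or scBAT 2, 1 without scBAT 1, scBAT 3, eWAT 1 or eWAT 3, 9 without iWAT 2 and 5 without iWAT 3. The scBAT count was 0 without iBAT 1, 1 without iBAT 2 or scBAT 2, 5 without iBAT 3 or eWAT 3, 4 without scBAT 1, 3 without iWAT 1, 18 without scBAT 3 and 15 without iWAT 2. The iWAT and eWAT counts were 638 and 403 without iWAT 1, 3979 and 2061 without iWAT 2, 723 and 693 without iWAT 3, 505 and 445 without eWAT 1, 697 and 580 without eWAT 2, and 694 and 457 without eWAT 3.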

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

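The alternatives that leave out a pair of libraries were chosen only after the results were seen, and the others were set in advance. Counts of results in this paragraph leave out iBAT against iWAT and iBAT against eWAT. A change of direction was counted only where the result passed the threshold in the reported or the alternative fit. For the named genes, 8561 of the results with a single library left out kept their side of the threshold without such a change, 56 newly passed and 455 no longer passed. Under the other alternatives set in advance 4840 stayed the same in this sense, 61 newly passed and 208 no longer passed. For the gene lists these were 1802, 36 and 22 with a library left out and 695, 8 and 72 under the other alternatives set in advance. Of these 72, 70 came from the estimated correlation of camera, under which 70 of 155 list results no longer passed. No alternative set in advance reversed a named gene or a list that passed in either fit. DESeq2 size factors, upper quartile scaling and no filter on low counts left every count of genes within 1.5 times the reported value.

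With each library left out in turn, the genes higher and lower in scBAT than in iBAT ranged from 3 to 121 and from 7 to 24, and those higher and lower in iWAT than in eWAT from 641 to 5326 and from 493 to 4997. Selective genes ranged from 0 to 9 in iBAT, 0 to 18 in scBAT, 505 to 3979 in iWAT and 403 to 2061 in eWAT. The fit shares a spread per gene over all depots, while the biological coefficient of variation was 42.8% in iWAT and 12.1% to 17.6% in the other depots. Contrasts with iWAT can thus have adjusted p-values that are too small. How far this accounts for the changes was not tested.

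The DESeq2 Wald test gave 181 higher and 29 lower genes in scBAT minus iBAT, 2492 lower in iWAT minus eWAT, and 12 and 47 genes selective for iBAT and scBAT. Limma-voom gave 21 higher and 8 lower in scBAT minus iBAT, 1426 higher in iWAT minus eWAT and 740 selective for iWAT. For both tools the cause was not tested. A block for the replicate number gave 10 higher and 8 lower in scBAT minus iBAT, and 0 and 4 genes selective for iBAT and scBAT, with fewer residual degrees of freedom. Residual correlations gave no sign of pairing by equal numbers, with a median of -0.044 for equal and 0.006 for unequal numbers. With 3 libraries per depot this does not exclude pairing. Fits of only the depots compared gave 127 higher and 27 lower in scBAT minus iBAT and 48 higher and 162 lower in iWAT minus eWAT, from 6 libraries each.

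Without iWAT 1 and 3, scBAT minus iBAT had 250 higher and 37 lower genes, iWAT minus eWAT 480 and 412, and 16, 195 and 374 genes were selective for iBAT, iWAT and eWAT. In that fit the iWAT minus eWAT differences of Arntl (-0.41), Cd24a (-0.07) and Sfn (-0.58) were reversed, and so were the camera directions of the lists pan-adipocyte (adjusted p = 0.173), oxidative phosphorylation (6.17e-15), tricarboxylic acid cycle (1.02e-07), fatty acid oxidation (2.49e-10), fatty acid synthesis (0.00153), triglyceride (0.259), developmental transcription factors (0.0122), collagen (0.116) and endothelium (0.865).

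Without scBAT 1 and 2, edgeR called 0 higher and 0 lower genes in scBAT minus iBAT, 2590 lower in scBAT minus iWAT, 2570 higher and 1945 lower in scBAT minus eWAT, 1293 and 829 in iWAT minus eWAT, and 0, 0, 696 and 521 genes selective for iBAT, scBAT, iWAT and eWAT. Aqp5 was reversed in scBAT minus eWAT (-0.54), as was the oxidative phosphorylation list in scBAT minus iBAT (adjusted p = 0.67). Without eWAT 2 and 3 there were 4 higher and 4 lower in scBAT minus iBAT, 2085 and 2092 in scBAT minus eWAT, 2156 and 2390 in iBAT minus eWAT, 23 and 69 in iWAT minus eWAT, and 0, 4, 9 and 57 selective genes. In these 3 alternatives a depot is left with 1 library, which is assumed to vary like the others, and the cause of the changes was not tested. Without the filter on low counts 4 of 10 median distances between libraries moved by more than the step from the middle of their range to its end. Small differences were mostly missed in simulated data: at 1.5-fold, 8 of 50 simulated genes were recovered in scBAT minus iBAT and 4 of 50 in iWAT minus eWAT.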

Other observations

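Some stress, secreted factor and matrix genes also differed between the white depots. Hspa1a and Hspa1b, which encode inducible heat shock proteins, were lower in iWAT than in eWAT by log2 differences of -2.21 (SE 0.35, adjusted p = 0.00378) and -1.98 (SE 0.28, adjusted p = 0.00231), with Hspa1b at 6.51 ± 1.1 CPM (SD, n = 3) in eWAT and 1.65 ± 0.327 in iWAT. Apln, the gene of the peptide hormone apelin, stood at 35.1 ± 1.03 CPM in eWAT and 10.5 ± 5.34 in iWAT (log2 difference -1.74, adjusted p = 0.0075). Fbn1, which encodes the microfibril protein fibrillin and the hormone asprosin cut from it, was lower in iWAT by -2.02 (adjusted p = 0.00969) and Dcn, a small proteoglycan of matrix, by -0.95 (adjusted p = 0.0109). Each of these genes passed without each of the 12 libraries in turn. Their lists moved less evenly: of the immediate early and stress genes 3 of 12 were lower, also adjusted over the list alone (camera adjusted p = 0.169), and of the adipokines and batokines 4 of 10 (5 over the list alone; camera adjusted p = 0.00175, and adjusted p = 0.511 with an estimated correlation). Of the collagen and matrix genes 4 of 16 were lower in both counts (camera adjusted p = 0.00566, and adjusted p = 0.642 with an estimated correlation), and without iWAT 1 and 3 the camera test placed that list higher (adjusted p = 0.116). Some epithelial transcripts were highest in eWAT 3: Epcam stood at 48.9 CPM there against 0.639 and 1.11 CPM in the other eWAT libraries, and Krt8, which is on the mesothelium list, at 98.1 against 18.8 and 16.7.

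Of the tests that follow, those of carry-over between libraries, of macrophage genes and of the other splits of the samples were chosen only after the result was seen. The lymph node and salivary gland tests were set before their genes were examined, except for a minimum of 10 counts in iWAT, added later, which left 6 stroma genes.

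Lymphocyte transcripts were high in iWAT 1 and 3. Carry-over from a library of another depot is excluded, since the highest median of B cell markers in such a library was 4.31 CPM, below the 11.8 CPM of iWAT 2. Transfer between the iWAT libraries was not tested. Lymph node tissue within the inguinal pieces is a candidate explanation: 6 genes of lymph node stroma had a median log2 ratio of 4.09 in iWAT 1 and 3 over iWAT 2 (2.95 to 4.55), next to 4.32 for B cell and 4.27 for T cell markers. No biological explanation was tested, as the design has no group within iWAT.

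Salivary gland transcripts were high in scBAT and in eWAT 2. In scBAT, gland tissue in the dissected pieces may be their source: 12 epithelial genes outside the fixed list had a median log2 ratio of 4.41 in scBAT 2 over the mean of iBAT, 3.26 in scBAT 1 and 0.71 in scBAT 3, and 11 of them had this order. For eWAT 2, the excess of salivary genes ran from 3.34% (counting interval 2.74 to 3.94) of the scBAT 2 level for Klk1 to 26.5% (26.0 to 26.9) for Smr3a, a ratio of 7.93. This argues against carry-over of the scBAT 2 library in a uniform share as the only source. Transfer of tissue or from other libraries was not tested. Ucp1 was also higher in eWAT 2, at 87.7 CPM against 24.2 and 24.8 in eWAT 1 and 3, as was Cidea, at 105 against 28.3 and 32.2. The source of the eWAT 2 transcripts stays open, and no biological explanation was tested.

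Macrophage markers were higher in scBAT than in iBAT. Macrophage markers moved by 0.65 on the log2 scale and endothelium markers by -0.22, a difference of 0.87 with a spread (SD) of 0.17. The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, so it cannot decide. A lower share of adipocytes in scBAT that raised all other cells alike would have moved both lists up. The values argue against that form as the whole cause. Whether endothelium falls along with adipocytes was not tested, so a lower share of adipocytes is not excluded. Whether the signal came with salivary gland or muscle tissue cannot be told apart from a property of the depot: scBAT 3, with the fewest transcripts of both, lay 0.43 above the highest iBAT library, but it is a single library. A difference in resident macrophages between the depots stays open and was not tested.

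Other splits of the libraries into groups of the same sizes were counted. For brown against white fat, 1 of 100 splits, the real one, gave as many called genes, 10333 against at most 4260 in the others. Each of the other splits mixed brown with white libraries, which places the brown and white difference within the groups. The splits therefore do not decide on chance for this contrast. For genes selective for a depot they do not decide on chance either, for the same reason, and at least 96 of the other splits gave 0 genes. Among the 100, 4 splits gave as many as the real 3 for iBAT, with 339 in the highest other, and whether that count reflects a structure of the samples was not tested. For scBAT (9 against 0), iWAT (1714 against 319) and eWAT (1059 against 56), 1 split, the real one, gave as many. For the pairs of depots the 10 splits are too few for a share under 0.05: the real and highest other counts were 49 and 1 for scBAT against iBAT, 9179 and 0 for scBAT against iWAT, 7731 and 0 for scBAT against eWAT, 9392 and 0 for iBAT against iWAT, 7998 and 0 for iBAT against eWAT, and 4277 and 3 for iWAT against eWAT, with 1 of 10 splits as large in each.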
